A study of Homo sapiens with 6 samples.

How the data were processed

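RNA was sequenced from 6 libraries of HEK293T cells, a transformed human embryonic kidney line, grown with 200 nM okadaic acid for 3 h. Okadaic acid inhibits the protein phosphatases that remove phosphate from UPF1, the RNA helicase at the centre of nonsense-mediated mRNA decay (NMD). Per the labels, 3 libraries came from an immunoprecipitation (IP) with an antibody against phosphorylated UPF1 (p-UPF1, replicates 3, 6 and 9) and 3 are titled pre-IP (replicates 1, 4 and 7). The antibody label of the pre-IP libraries reads rabbit IgG, the mock antibody of the protocol, so the labels conflict on whether the control is RNA taken before the IP or RNA from a mock IP. The control is called pre-IP here, by its title. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Per the labels' protocols, RNA was treated with DNase, depleted of ribosomal RNA, dephosphorylated, ligated to a 3' adapter, phosphorylated and ligated to a 5' adapter (33 nt each), reverse transcribed and amplified over 20 PCR cycles, and inserts above 20 bp were size-selected. Such a library records short RNAs and decay fragments whole, so abundant small structured RNAs compete with mRNA fragments for reads.

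The deposited table holds whole-number counts of reads per gene symbol, with 1 column per library and no normalization. Per the submitters' processing notes the tools were cutadapt 1.15, STAR 2.5.2b and featureCounts of Subread 1.5.0p3, with the hg19 build. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads of overlapping genes, of a gene and its antisense partner, and of near-identical copies such as SMG1 and its pseudogenes or the processed pseudogenes of ribosomal protein genes therefore cannot be told apart. The table has 26364 genes, of which 11319 had no count in any library, and every column was used.

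Total counts per library were 1179369, 600244 and 945005 in pre-IP (replicates 1, 4 and 7) and 2057647, 1840194 and 905926 in p-UPF1 IP (replicates 3, 6 and 9). No molecular identifiers are described, and PCR reads without them are not independent molecules, so every interval and floor given covers counting error only. Where a group had no count of a gene, the fold is a bound against 3 counts over that group. Where a group had 1 to 3 counts, the ratio is given with its exact (Clopper-Pearson) 95% interval.

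Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM scaling) and adjusted by the Benjamini-Hochberg method at 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. The gene lists, fixed before the data were examined along with the main design and the rule for named genes, were tested with camera of limma 3.58.1 (preset correlation 0.01, and again with an estimated correlation), adjusted over the 19 lists with at least 3 tested members. Members were also adjusted over the list alone. Of the other lists, mitochondrially encoded mRNAs had 0 members in the table, and markers of other cell types (blood, liver, fibroblast, muscle, epidermis) had 20 members in the table and 0 tested, with a mean share of counts of 0.00036% in pre-IP and 0.000684% in p-UPF1 IP. Composition was compared as shares of all counts with a two-sided exact permutation test, in which 3 libraries against 3 cannot give a p below 0.1. On simulated counts for the 8070 tested genes, 200 of them set as changed, the test recovered 6.78% of 59 genes changed 2-fold, 64.2% of 53 changed 4-fold and 98.3% of 59 changed 8-fold, and 6 of its 102 calls were false. The data gave 1591 calls, and with fewer changed genes the adjusted threshold is stricter. The simulated shares may therefore understate recovery in the data.

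The named genes were UPF1, GADD45A, GADD45B, ATF4 and GAS5, the 8 largest increases and 8 largest decreases past the threshold among genes at or above the median mean log2 CPM whose groups did not overlap, and the 2 most abundant members of each list. Other list members were named as examples after their values were seen. Gene types, transcript lengths, GC content and the genes that lie inside others were matched by symbol to GENCODE release 29 and to a RefSeq annotation of GRCh38, a later build than the table's, so no coordinates are given. No type was found for 1058 of the 26364 symbols. Transcript length and GC were had for 7425 of the 7653 tested protein-coding genes (97.0%).

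The alternatives were RLE and upper-quartile scaling, library totals alone, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, robust quasi-likelihood, glmTreat against a fold of 1.5, a replicate block by triplet of label numbers, the 10 most counted genes left out, the small structured RNAs left out, each library left out in turn, and camera with an estimated correlation. Chosen after seeing the data were removal of the transcript length, GC or 3' UTR length trend of each library, protein-coding genes alone, genes holding a structured RNA gene left out, libraries thinned to equal protein-coding reads, and, for the cytosolic ribosomal proteins and the respiratory chain, camera with an estimated correlation after removal of the length trend. Tables and plots were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.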

Results

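Short RNAs and RNA decay fragments were sequenced from okadaic acid-treated HEK293T cells before (pre-IP, n = 3) and after (p-UPF1 IP, n = 3) immunoprecipitation of phosphorylated UPF1, as the sample titles have it. UPF1 is phosphorylated by SMG1 on mRNAs that undergo NMD, and the comparison asks which RNAs are enriched or depleted with p-UPF1 relative to the control. The control also carries a rabbit IgG label, so it can be read as input RNA or as a mock IP. Libraries held from 600244 to 1179369 counts in pre-IP and from 905926 to 2057647 in p-UPF1 IP. Log2 CPM correlated across genes at r = 0.74 to 0.79 between pre-IP libraries, at 0.91 to 0.92 between p-UPF1 IP libraries and at 0.65 to 0.72 between the groups.

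The p-UPF1 IP libraries held a larger share of protein-coding counts and a smaller share of small structured RNAs. Protein-coding genes took 28.2% ± 4.93 (SD, n = 3) of counts in pre-IP and 61.6% ± 8.54 in p-UPF1 IP (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows, Benjamini-Hochberg 0.128), with 22.7% to 32.2% in the pre-IP and 54.6% to 71.1% in the p-UPF1 IP libraries. The share of spliceosomal snRNA genes was 8.29% ± 2.43 in pre-IP and 0.787% ± 0.151 in p-UPF1 IP, and that of other small structured RNAs, such as RNase P RNA and vault RNAs, 11.4% ± 1.11 and 1.5% ± 0.423 (exact p = 0.1 for both). The share of snoRNA genes, which guide rRNA modification, was 44.0% ± 6.00 and 32.1% ± 9.06 (exact p = 0.2), and that of the HIST histone genes 3.13% ± 1.51 and 3.11% ± 1.36 (exact p = 1). The 10 NMD factor genes took 0.0122% ± 0.0046 and 0.123% ± 0.0242, and the 15 NMD-target genes 0.0329% ± 0.0077 and 0.190% ± 0.0183 (exact p = 0.1 for both). Every other mRNA list except replication-dependent histones and markers of other cell types also rose in share (exact p = 0.1 for each). The mean share rose 10.1-fold for NMD factors and 5.78-fold for NMD targets. It rose 3.70-fold for ZNF genes, 3.20-fold for glycolytic enzymes, 1.40-fold for cytosolic ribosomal proteins and 2.18-fold for all protein-coding genes. Some counts of protein-coding symbols can come from structured RNA genes inside them, as TMEM107 holds SNORD118. Protein-coding genes with no such gene inside took 22.4% ± 4.46 and 53.8% ± 8.01. The 10 most counted genes of each library held 32.6% to 36.2% of its counts in pre-IP and 7.46% to 12.7% in p-UPF1 IP.

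**Figure D1:**
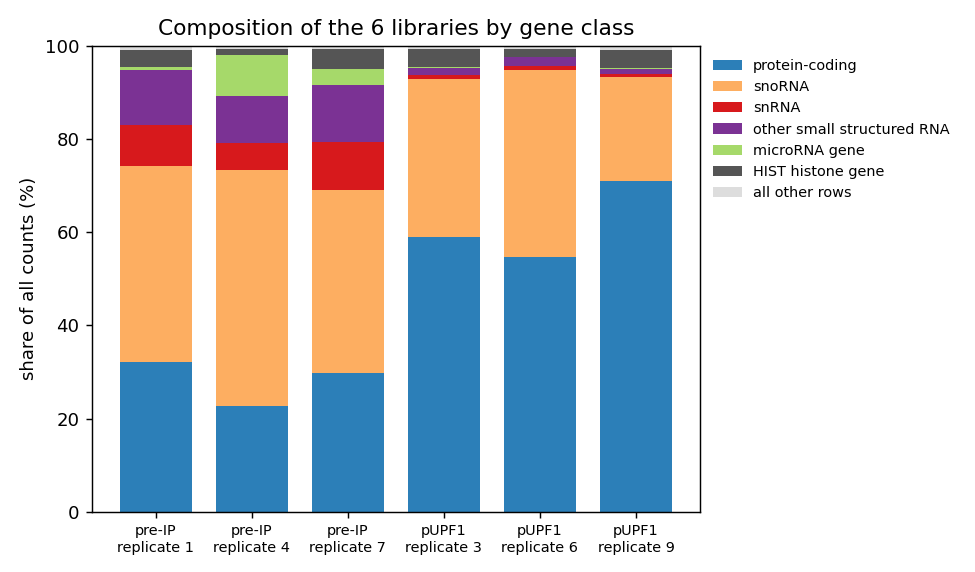
Share of all counts (y axis, %) by gene class in each of the 6 libraries (x axis, stacked bars). Protein-coding genes average 28.2% in the 3 pre-IP libraries and 61.6% in the 3 p-UPF1 IP libraries, and other small structured RNAs 11.4% and 1.5%.

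Of 8070 genes tested, 1591 changed, 711 higher and 880 lower in p-UPF1 IP (edgeR quasi-likelihood F-test, Benjamini-Hochberg 0.05). Of the 7653 protein-coding genes tested, 701 were higher and 587 lower. Of the 238 snoRNA, 7 snRNA, 43 HIST histone and 22 microRNA genes tested, 0 were higher and 205, 7, 34 and 19 lower. The largest increases included SYMPK, a scaffold of mRNA 3'-end processing, with 1 count in pre-IP and 473 in p-UPF1 IP (a ratio of 99.3, 95% counting interval 17.7 to 3931). DHTKD1, a mitochondrial dehydrogenase subunit, rose by 3.69 on the log2 scale (SE 0.56, adjusted p = 0.000275). ZFC3H1, a factor of nuclear exosome targeting, rose by 3.47, CEP135, a centriole protein, by 3.45, BOD1L1 by 3.35, CAMSAP2, a microtubule minus-end protein, by 3.19, and the histone methyltransferase KMT2D by 3.17. These genes were thinly counted in pre-IP, with 6 counts of CEP135 and 15 of KMT2D over the 3 libraries. The largest decreases included small non-coding RNAs. MIR7641-2 fell from 83760 counts to 100 (log2 fold change -12.74, SE 1.65), but its pre-IP libraries held 4299, 50440 and 29021 counts. RPPH1, the RNA of RNase P, had a log2 fold change of -8.04 (SE 1.19, adjusted p = 0.000225), and the vault RNA VTRNA1-2 one of -7.01 (SE 0.59, adjusted p = 8.1e-07). The Y RNA RNY4 had 349 counts in pre-IP and 1 in p-UPF1 IP (a ratio of 1662, 95% counting interval 296 to 65840). CTC1, a telomere replication gene, and LINC00324 fell (-7.30 and -7.13), and they hold 3 and 4 tRNA genes inside. LOC102577426 and LOC101926933, with no gene type found, fell as well (-7.98 and -7.77).

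The split of calls depends on the scaling. With library totals alone 5030 genes were called, 4874 higher and 156 lower, and the median log2 fold change of the tested genes was 1.63 in place of 0.10 with TMM, so changes are relative to that median. Of 106 named genes 27 changed sign on that scale, and of the 80 past the threshold 25 lost their call, 13 of them with a change of sign. The other 12 had log2 fold changes closer to 0 (MTHFD2 -0.0056, MALAT1 -0.98, HIST1H2BK -0.054, SNORA46 -0.76, TPT1 -0.18, DNAJB11 -1.08, SEP15 -0.66, C11orf31 -0.85, GPX4 -0.15, MRPL22 -0.98, ZNF587 -0.45 and ZNF786 -0.51), with adjusted p from 0.0693 (MALAT1) to 0.989 (MTHFD2). Of the 53 named calls that could be tested with a trend of the transcripts removed, 16 were lost with the length trend removed (H2AFZ, ZNF503, SLC7A11, CCNL1, PTBP1, SRSF9, SESN2, SLC38A2, PCK2, MANF, IER2, EGR3, EEF1B2, H2AFV, GPX4 and MRPL49). With the GC trend removed 10 were lost (ZNF503, UPF1, PTBP1, SESN2, PCK2, P4HB, IER2, EGR3, MRPL49 and MRPL4), and with the 3' UTR trend removed 9 (ZNF503, CLK1, CCNL1, PTBP1, PCK2, IER2, EGR3, MRPL49 and MRPL4). Some of these log2 fold changes moved little. With the length trend removed MRPL49 went from 1.21 to 1.25, PCK2 from 1.23 to 1.14, CCNL1 from 1.05 to 0.95 and IER2 from 1.71 to 1.49. With the 3' UTR trend removed PCK2 was at 1.23 again and CLK1 went from 1.11 to 1.04. Their lost calls do not show that the trend lay behind the change, nor do those of EGR3 and MRPL4, whose folds rest on 3 counts in pre-IP. The count of calls was 791, 950 and 908 without p-UPF1 IP replicate 3, 6 or 9. Of the 1591 changed genes, 1557 had groups that did not overlap. The test picked these genes by the difference between the same libraries, so that count is no separate evidence. Among all tested genes the share was 39.7%, against 10% by chance for a gene unrelated to the grouping.

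Of 9 genes of the NMD pathway tested, 4 were higher in p-UPF1 IP and 0 lower. UPF1 itself rose from 31.1 ± 15.7 to 105 ± 26.1 CPM (SD, n = 3, log2 fold change 1.70, SE 0.38, adjusted p = 0.0046). SMG1, the kinase that phosphorylates UPF1, rose by 3.39 (SE 0.39, adjusted p = 2.4e-05), from 20.2 ± 13.7 to 239 ± 44.3 CPM, though reads shared with its pseudogenes leave that value uncertain. SMG5, which binds p-UPF1, rose by 1.53 (SE 0.35, adjusted p = 0.0051). Adjusted over the list alone 4 rose and 0 fell as well, and limma-voom called 5 over all genes. UPF2 and SMG6 had log2 fold changes of 1.32 and 1.73, neither past the threshold. The list median was 1.53 (camera adjusted p = 0.00054, adjusted p = 0.141 with an estimated correlation). The call of UPF1 was lost with the GC trend removed (log2 fold change 0.92, adjusted p = 0.108).

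Of 14 mRNAs known as NMD targets, 4 rose and 0 fell over all genes, and 6 rose and 0 fell adjusted over the list alone. The 4 were the stress transcription factor ATF3 (2.10, SE 0.44, adjusted p = 0.0030), the growth-arrest genes GADD45A (1.82, SE 0.56, adjusted p = 0.0311) and GADD45B (1.74, SE 0.44, adjusted p = 0.0099), and the cystine transporter SLC7A11 (1.35, SE 0.32, adjusted p = 0.0063). ATF4 went from 147 ± 39.5 to 257 ± 29.2 CPM (0.82, SE 0.30, adjusted p = 0.0607) and DDIT3 had a log2 fold change of 1.43 (adjusted p = 0.0612). ATF4 was called in 9 of 24 alternatives (adjusted p = 3.8e-05 with library totals alone to 0.462 with the GC trend removed) and DDIT3 in 6 of 24 (0.000172 with library totals alone to 0.232 in thinned libraries), both of them without pre-IP replicate 4 (0.0308 and 0.0163). UPP1 had -1.80 (adjusted p = 0.112). The list median of 0.73 did not pass camera (adjusted p = 0.0543, adjusted p = 0.234 with an estimated correlation). It passed in 12 of 23 alternatives, among them the length trend removed (0.54, the lowest adjusted p of 0.00713) and those without pre-IP replicate 4 (0.044) or p-UPF1 IP replicate 3 (0.0374) or 9 (0.011). The highest was 0.200, without pre-IP replicate 7. The libraries of the groups overlapped for both GADD45 genes. GADD45A lost its call without pre-IP replicate 4 (adjusted p = 0.058) or 7 (0.0855) or p-UPF1 IP replicate 3 (0.0722) or 6 (0.208), GADD45B without p-UPF1 IP replicate 3 (0.0577) or 6 (0.0536), and SLC7A11 with the length trend removed (0.57, adjusted p = 0.235).

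**Figure D2:**
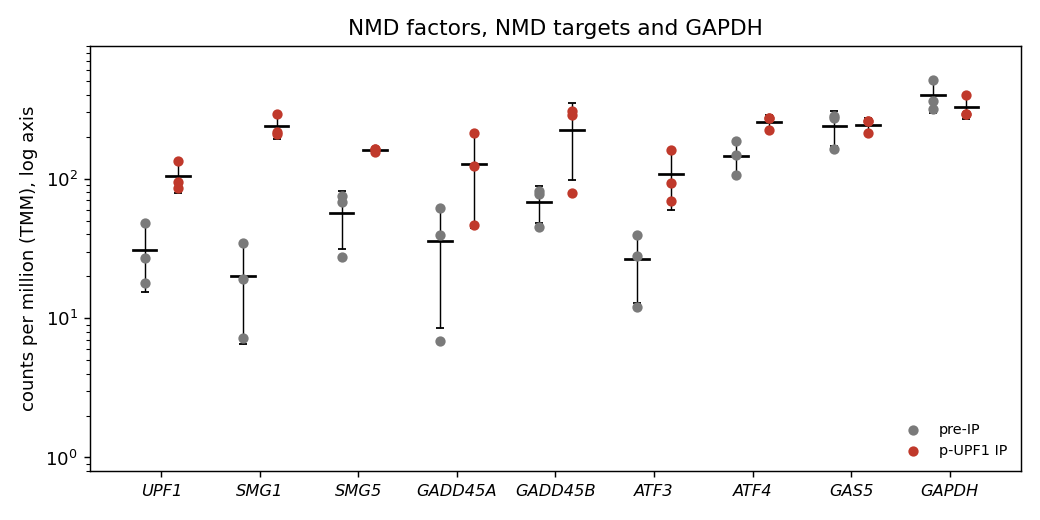
TMM-scaled CPM (y axis, log scale) of 9 genes (x axis) in the 3 pre-IP (grey) and 3 p-UPF1 IP (red) libraries. Points are libraries, thick lines means and error bars SD. UPF1 averages 31.1 and 105 CPM, SMG1 20.2 and 239 CPM, and GAS5 239 and 244 CPM.

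The spliced hosts of snoRNAs, a class of non-coding NMD substrates, moved both ways. Of 17 tested, 1 rose (SNHG15, 1.90, adjusted p = 0.0070) and 4 fell (SNHG3, -2.99, adjusted p = 0.000261, SNHG6, -1.01, SNHG5, -0.95, and SNHG16, -0.80), in the same numbers adjusted over the list alone. GAS5 had 239 ± 66.4 and 244 ± 27.9 CPM (log2 fold change 0.04, adjusted p = 0.941) and LRRC75A-AS1 -0.15 (adjusted p = 0.758). The list median was -0.15 (camera adjusted p = 0.348) and 1.43 with library totals alone, where SNHG5, SNHG6 and SNHG16 also turn positive. Except for SNHG3, these calls were lost without at least 1 library, with highest adjusted p values of 0.0566 for SNHG15 (without p-UPF1 IP replicate 6), 0.207 for SNHG6 (without pre-IP replicate 1), 0.158 for SNHG5 (without p-UPF1 IP replicate 3) and 0.164 for SNHG16 (without p-UPF1 IP replicate 6).

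Small structured RNAs were lower as a class. Of 243 snoRNAs and snRNAs tested, 210 fell and 0 rose, and 228 fell adjusted over the list alone, with a median log2 fold change of -1.95 (camera adjusted p = 8.2e-69, adjusted p = 0.157 with an estimated correlation). All 7 snRNAs fell, among them RNU6ATAC and RNU4ATAC of the minor spliceosome (-6.59, SE 0.79, and -5.97, SE 0.66) and RNU11 (-4.50, SE 0.92). With library totals alone the list median was -0.41. SNORA46 fell by 2.39 (SE 0.76, adjusted p = 0.0342), a call that was lost with library totals alone (adjusted p = 0.138) and without each library in turn except p-UPF1 IP replicate 9, with a highest adjusted p of 0.182 without p-UPF1 IP replicate 3. Of 7 other structured RNAs (RNase P, RNase MRP, Y and vault RNAs), 6 fell and 0 rose, 7 adjusted over the list alone, and the median was -7.01, or -6.60 with RNY5 at its bound (camera adjusted p = 1.4e-28, adjusted p = 0.0059 with an estimated correlation). RNY5 had 33 counts in pre-IP and 0 in p-UPF1 IP, at least 52.4-fold lower. RMRP, the RNA of RNase MRP, had a log2 fold change of -1.83 (SE 0.68, adjusted p = 0.0677). Of the 3 nuclear long non-coding RNAs tested, NEAT1 (-3.52, SE 0.38) and MALAT1 (-2.40, SE 0.48) fell and TUG1 (1.90, SE 0.32) rose (MALAT1 was not past the threshold with library totals alone, adjusted p = 0.0693), with the same calls adjusted over the list alone and no call for the list (camera adjusted p = 0.125). The list passed in 7 of 19 alternatives, among them those without pre-IP replicate 4 (0.0108) or 7 (0.0205) or p-UPF1 IP replicate 3 (0.0284) or 6 (0.0368). The highest was 0.265, in thinned libraries. The annotation used here types TUG1 as protein-coding, so it is also counted among the protein-coding genes that rose. It also places the small RNA gene MASCRNA inside MALAT1, so the counts of MALAT1 may include reads of that RNA.

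Replication-dependent histone mRNAs, which end in a stem-loop in place of a poly(A) tail, fell relative to other genes. Of 43 tested, 34 fell and 0 rose, and 37 fell adjusted over the list alone (median -1.62, camera adjusted p = 1.0e-16, adjusted p = 0.286 with an estimated correlation). HIST1H4C fell by 2.88 (SE 0.51) and HIST1H4H fell by 2.68 (SE 0.42), while HIST1H2BD had a log2 fold change of -0.67 (adjusted p = 0.319). HIST1H2BK fell by 1.57 (adjusted p = 0.0325), a call lost without pre-IP replicate 1 or 7 or p-UPF1 IP replicate 6 or 9 (highest adjusted p = 0.148, without p-UPF1 IP replicate 6). With library totals alone the list median was -0.10. Of 8 replication-independent histones, 3 fell and 0 rose (H3F3B, -1.23, H2AFZ, -1.22, and H2AFV, -1.17), 3 fell and 1 rose adjusted over the list alone, and the median of -0.59 (camera adjusted p = 0.0752) turned to 0.99 with library totals alone (adjusted p = 0.681). The list passed in 6 of 23 alternatives, with the lowest adjusted p of 0.000405 with the GC trend removed (-1.06). H2AFZ lost its call without p-UPF1 IP replicate 3 (adjusted p = 0.0915), and H2AFV without 4 of the libraries (highest adjusted p = 0.0951, without p-UPF1 IP replicate 3). With the length trend removed H2AFZ had a log2 fold change of -0.31 (adjusted p = 0.458) and H2AFV one of 0.081 (adjusted p = 0.890), and with library totals alone H3F3B, H2AFZ and H2AFV were positive.

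Short mRNAs of ribosomes and of the respiratory chain were lower by TMM. Of 78 cytosolic ribosomal protein mRNAs, 45 fell and 0 rose, and 52 fell adjusted over the list alone (median -1.22, or 0.39 with library totals alone, camera adjusted p = 3.6e-21, adjusted p = 0.210 with an estimated correlation). The log2 fold change of RPS12 was -3.50 (SE 0.33), of RPL39 -3.20 (SE 0.33), of RPS23 -3.06 (SE 0.36) and of RPLP1 -2.96 (SE 0.35), while RPS4X and RPL5 had log2 fold changes of -0.31 (adjusted p = 0.60) and -1.09 (adjusted p = 0.0721). Of these, RPS12, RPL39 and RPL5 hold snoRNA genes inside, so their counts may include snoRNA reads. At the preset correlation the list passed camera in 23 of 23 alternatives, among them genes holding a structured RNA gene left out. With the length trend removed the median of these 78 mRNAs was -0.53 (camera adjusted p = 1.2e-05, adjusted p = 0.478 with an estimated correlation). Of 68 nuclear-encoded respiratory chain genes, 34 fell and 0 rose, and 37 fell adjusted over the list alone (median -1.37, or 0.21 with library totals alone, camera adjusted p = 5.0e-16, adjusted p = 0.141 with an estimated correlation). With the length trend removed the median of the 56 members with a known length was -0.70 (camera adjusted p = 3.4e-05, adjusted p = 0.205 with an estimated correlation). The small subunit genes NDUFB1, COX7A2, NDUFA1 and UQCRH fell (-5.19, -3.90, -3.64 and -3.60), while ATP5B and ATP5A1 had log2 fold changes of 0.30 and -0.42, neither past the threshold. Of 62 mitochondrial ribosomal protein genes, 13 fell and 2 rose, and 16 fell and 5 rose adjusted over the list alone (median -0.70, or 0.84 with library totals alone, camera adjusted p = 0.0037, adjusted p = 0.154 with an estimated correlation). This last list lost its call with the length trend removed (median -0.37, adjusted p = 0.498) and in thinned libraries (-0.52, adjusted p = 0.567). It passed in the other 21 of 23 alternatives (lowest adjusted p = 0.00026). MRPL22 fell by 2.58. The risers were MRPL49 (1.21, adjusted p = 0.0414) and MRPL4, with 3 counts in pre-IP and 101 in p-UPF1 IP (a ratio of 7.07, 95% counting interval 2.35 to 34.8), and each lost its call without 5 of the 6 libraries (highest adjusted p = 0.196 without p-UPF1 IP replicate 3 for MRPL49 and 0.153 without p-UPF1 IP replicate 9 for MRPL4). MRPL37 and MRPL3 had log2 fold changes of 0.34 and -0.75, neither past the threshold.

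Of 13 selenoprotein mRNAs, in which a UGA codon is read as selenocysteine, 7 fell and 1 rose, and 8 fell and 1 rose adjusted over the list alone (median -1.04, or 0.54 with library totals alone, camera adjusted p = 0.0037, adjusted p = 0.141 with an estimated correlation). SEP15 (-2.20, SE 0.33), C11orf31 (-2.42, SE 0.58), GPX4 (-1.71, SE 0.50) and VIMP (-1.04, SE 0.34) fell, and TXNRD1 had -0.87 (adjusted p = 0.0585). With library totals alone these 4 calls were lost, with SEP15 at -0.66 (adjusted p = 0.167), C11orf31 at -0.85 (0.251), GPX4 at -0.15 (0.827) and VIMP positive. The list lost its call with the length trend removed (median -0.61 over the 5 members with a known length, adjusted p = 0.395), where GPX4 had -0.76 (adjusted p = 0.336), and with the 3' UTR trend removed (-0.70, adjusted p = 0.104). It passed in the other 21 of 23 alternatives (lowest adjusted p = 0.000672). SELO had 0 counts in pre-IP and 81 in p-UPF1 IP, at least 5.67-fold higher. Calls were lost for C11orf31 without pre-IP replicate 1 (adjusted p = 0.0709), for GPX4 without 3 libraries (highest adjusted p = 0.158, without pre-IP replicate 1), for SELO without p-UPF1 IP replicate 9 (0.0502), and for VIMP without each library except pre-IP replicate 1 (highest adjusted p = 0.178, without p-UPF1 IP replicate 6).

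Of 16 mRNAs of translation with a terminal oligopyrimidine tract, 3 fell (TPT1, -1.74, EEF1B2, -1.33, and EIF4B, -1.02) and 0 rose, 3 and 1 adjusted over the list alone, and EEF1A1 had -0.35 (list median -0.12, or 1.45 with library totals alone, camera adjusted p = 0.390). TPT1 lost its call without p-UPF1 IP replicate 3 (adjusted p = 0.0622), and EEF1B2 without the same library (0.0527) and with the length trend removed (-0.54, adjusted p = 0.209). EIF4B lost its call without 4 libraries (highest 0.082, without p-UPF1 IP replicate 9). Of 25 splicing regulators with NMD isoforms, SRSF11 (1.64), CLK1 (1.11), CCNL1 (1.05) and PTBP1 (0.996) rose and SRSF9 (-1.46), SRSF5 (-1.15) and SRSF3 (-1.09) fell, or 5 and 3 adjusted over the list alone, while SRSF2 and HNRNPH1 had 0.42 and -0.18 (list median 0.09, camera adjusted p = 0.586). With library totals alone the list median was 1.65 and passed camera (adjusted p = 0.041), the only one of 23 alternatives in which it did (highest adjusted p = 0.888, without pre-IP replicate 4). SRSF11 alone of these 7 kept its call without each library, and the highest adjusted p was 0.174 for CCNL1 without p-UPF1 IP replicate 3, 0.161 for CLK1 and 0.162 for PTBP1 without p-UPF1 IP replicate 9, 0.0821 for SRSF3 and 0.0784 for SRSF9 without p-UPF1 IP replicate 3, and 0.0522 for SRSF5 without p-UPF1 IP replicate 6. Those 3 falling genes turn positive with library totals alone. With the length trend removed SRSF9 had -0.84 (adjusted p = 0.143) and PTBP1 0.72 (0.126), and with the GC trend removed PTBP1 had 0.36 (0.459).

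Of 20 genes transcribed by ATF4 in the integrated stress response, STC2 (2.03), SESN2 (1.44), SLC38A2 (1.27) and PCK2 (1.23) rose and the mitochondrial folate enzyme MTHFD2 (-1.57, SE 0.30, but -0.0056 with library totals alone) fell, or 4 and 2 adjusted over the list alone, and ASNS had -0.43 (list median 0.52, camera adjusted p = 0.240, 0.0111 with library totals alone to 0.917 with the GC trend removed, past in 2 of 23 alternatives). SLC38A2 lost its call without p-UPF1 IP replicate 6 (adjusted p = 0.097) and PCK2 without 5 libraries (highest 0.238, without p-UPF1 IP replicate 9). With the GC trend removed SESN2 (adjusted p = 0.195) and P4HB (0.115) lost theirs. Of 14 ER chaperones, P4HB rose by 1.27 and DNAJB11 (-2.65) and MANF (-1.09) fell, or 1 and 2 adjusted over the list alone, while HSPA5 and CANX had 0.70 and -0.93 (list median -0.26, or 1.28 with library totals alone, camera adjusted p = 0.390). MANF lost its call without 4 libraries (highest 0.117, without pre-IP replicate 1) and with the length trend removed (-0.40, adjusted p = 0.44), and with library totals alone DNAJB11 lost its call (-1.08, adjusted p = 0.0889) and MANF turned positive. Of 21 AU-rich immediate-early mRNAs, IER2 rose by 1.71, and EGR3 had 3 counts in pre-IP and 112 in p-UPF1 IP (a ratio of 7.84, 95% counting interval 2.61 to 38.6). Adjusted over the list alone 0 of them rose and 0 fell (4 had an unadjusted p under 0.05, and over all genes DESeq2 called 2 and limma-voom 1), JUN and MCL1 had 0.90 and -0.11, and the list median was 0.16 (camera adjusted p = 0.533). The IER2 and EGR3 calls were lost without 4 and 5 libraries (highest 0.245 and 0.199, without p-UPF1 IP replicate 6). Of 16 glycolytic enzymes 0 rose and 0 fell in edgeR, over all genes and adjusted over the list alone, against 5 at an unadjusted p under 0.05 and, over all genes, 1 lower in each of DESeq2 and limma-voom, and ENO1 and GAPDH had 0.63 and -0.27 (list median 0.13, camera adjusted p = 0.586). Of 156 ZNF zinc-finger genes, 17 rose and 2 fell (ZNF587, -2.04, and ZNF786, -2.03), or 15 and 1 adjusted over the list alone (median 0.70, camera adjusted p = 0.0037, adjusted p = 0.155 with an estimated correlation). The list lost its call with the length trend removed (median 0.24, adjusted p = 0.0742), with library totals alone (2.21, adjusted p = 0.118) and with no filter on low counts (0.72, adjusted p = 0.0698). It passed in the other 20 of 23 alternatives (lowest adjusted p = 0.00293). ZNF503 rose by 1.09 (adjusted p = 0.0491) and ZNF664 had -0.42. ZNF503 lost its call without 5 libraries (highest 0.228, without p-UPF1 IP replicate 6) and with the GC trend removed (0.27, adjusted p = 0.656). ZNF587 lost its call without 3 (highest 0.0822, without p-UPF1 IP replicate 3) and ZNF786 without each of the 6 (highest 0.226, without p-UPF1 IP replicate 3).

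**Figure D3:**
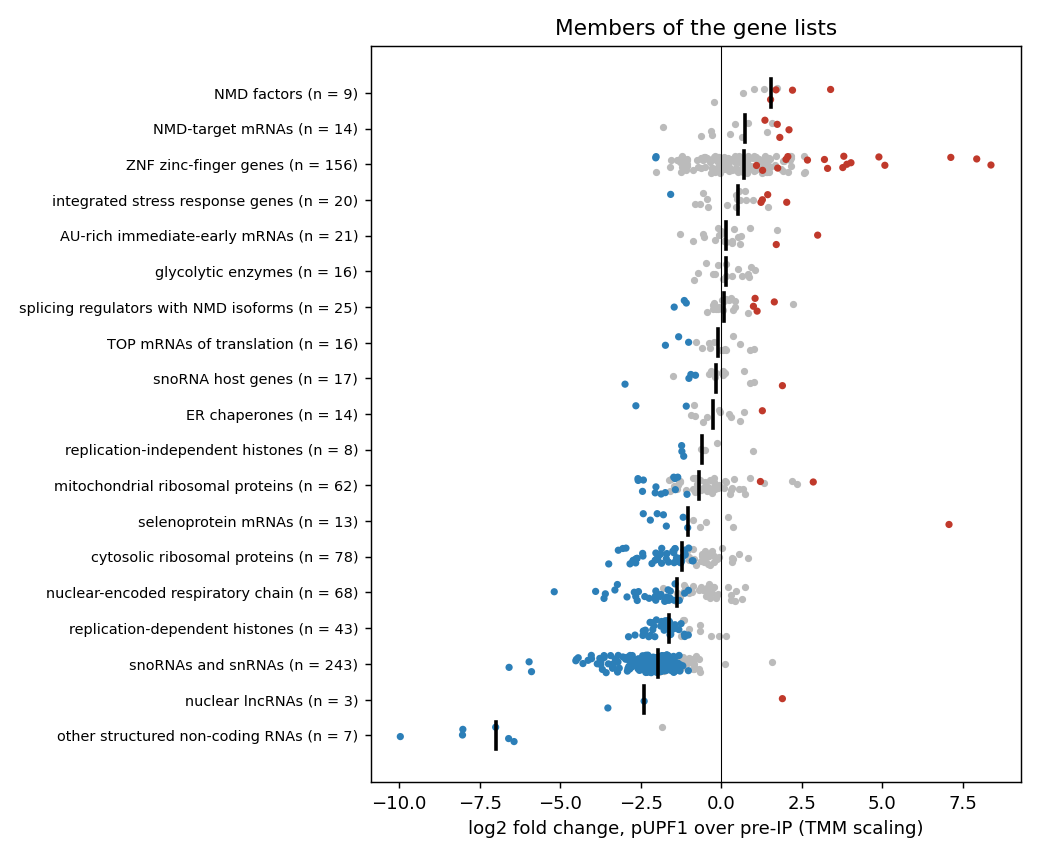
Log2 fold change, p-UPF1 IP over pre-IP with TMM scaling (x axis), of the tested members of 19 gene lists (y axis). Points are genes, red (higher) or blue (lower) where past the threshold and grey otherwise, black bars are list medians, and genes with 0 counts in a group (SELO, RNY5 and 3 ZNF genes) stand at fitted values. NMD factors have a median of 1.53 and other structured RNAs one of -7.01, and the medians of 8 lists change sign with library totals alone.

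Longer transcripts were more enriched. Across 7425 protein-coding genes, which are not independent replicates, the log2 fold change had a Spearman rho of 0.335 with transcript length (0.219 to 0.335 over the 9 pairs of a p-UPF1 IP and a pre-IP library) and of 0.204 with GC content (-0.0084 to 0.237, near 0 in the 3 pairs with pre-IP replicate 4). In the shortest decile (344 to 1549 nt) 12 genes rose and 212 fell, with a median log2 fold change of -0.77, and in the longest (7886 to 34526 nt) 173 rose and 16 fell, with a median of 0.72. Without pre-IP replicate 4 the rho with length was 0.269, and it was lower still with no filter on low counts (given below).

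**Figure D4:**
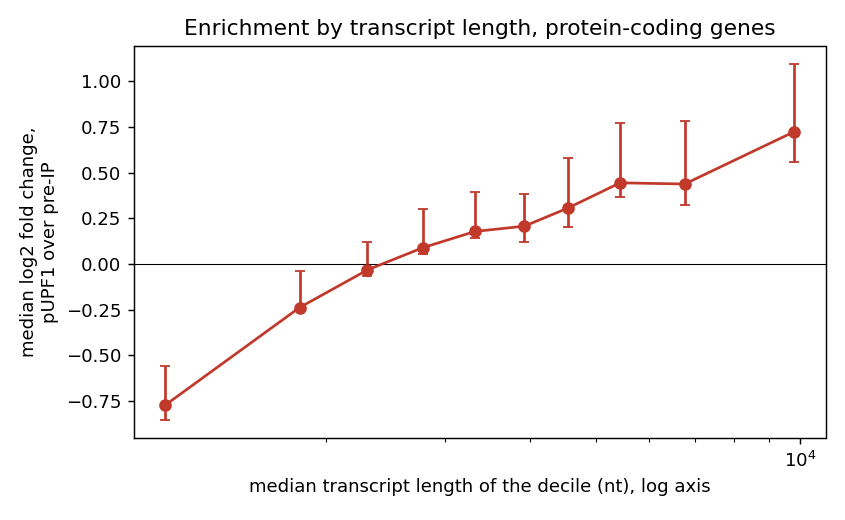
Median log2 fold change, p-UPF1 IP over pre-IP with TMM scaling (y axis), of protein-coding genes by decile of transcript length (x axis, median nt of the decile, log scale). Bars span the medians of the 9 pairs of libraries, and points run from -0.77 in the shortest decile to 0.72 in the longest.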

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

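The removal of the length, GC and 3' UTR trends, protein-coding genes alone, the thinned libraries the genes holding structured RNA genes left out, and the estimated correlation after removal of the length trend (cytosolic ribosomal proteins, respiratory chain) were chosen after the results were seen. Of the 1591 calls, 1207 to 1591 were tested in each alternative, and of those tested none changed sign except 295 of 1591 with library totals alone and 11 of 1237 with the length trend removed. RLE (1616 calls), upper-quartile scaling (1617), the stricter filter (1627), DESeq2 (1783), limma-voom (1682), robust quasi-likelihood (1578), the 10 most counted genes left out (1568), structured RNAs left out (1299), genes holding one left out (1496) and protein-coding genes alone (1221) stayed within 1.5 times the main count. So did the replicate block by triplet of label numbers (1656), in which each library correlated best with its own triplet (r = 0.092, 0.172 and 0.102), a hint from the data and not the design. Library totals alone gave 5030 calls, 4874 higher and 156 lower, no filter 1101 higher, glmTreat 971, 389 higher and 582 lower, length trend removed 864, 296 higher and 568 lower, GC trend removed 453 higher, 3' UTR trend removed 416 higher, and thinned libraries 431 higher, with fewer genes tested. Leaving out 1 library gave 791 to 1628 calls, 273 to 795 higher and 518 to 833 lower, and 9 to 11 lists past camera. The rho with length moved to 0.202 with no filter, 0.400 with the GC trend removed, 0.270 with the 3' UTR trend removed and 0.406 in thinned libraries, and to 0.269 to 0.339 over the libraries left out; the rho with GC was 0.320 with the length trend removed. The number of lists past camera was 9, with 4 after removal of the length trend, which leaves protein-coding members alone, and 1 with an estimated correlation. With library totals alone these log2 values turned positive: MCL1 1.43, RPS4X 1.29, RPL5 0.50, CANX 0.62, GAPDH 1.36, ASNS 1.21, MRPL3 0.82, ATP5A1 1.19, HIST1H2BD 0.89, H2AFZ 0.35, H3F3B 0.32, TXNRD1 0.68, VIMP 0.54, LRRC75A-AS1 1.43, HNRNPH1 1.38, EEF1A1 1.24, ZNF664 1.10, SNHG5 0.64, SNHG6 0.51, SNHG16 0.77, SRSF3 0.47, SRSF5 0.43, SRSF9 0.085, MANF 0.47, EEF1B2 0.26, EIF4B 0.52, H2AFV 0.40; and the list medians snoRNA hosts 1.43, replication-independent histones 0.99, cytosolic ribosomal proteins 0.39, terminal oligopyrimidine mRNAs 1.45, mitochondrial ribosomal proteins 0.84, respiratory chain 0.21, selenoproteins 0.54 and ER chaperones 1.28, because the scale itself moved. Other reversals were, except for H2AFV, of values short of the threshold: with no filter MCL1 0.066, LRRC75A-AS1 0.024, snoRNA hosts 0.11 and terminal oligopyrimidine mRNAs 0.058; with structured RNAs left out GAS5 -0.000635; with the length trend removed RPS4X 0.039, H2AFV 0.081 and splicing regulators -0.084; with the GC trend removed ENO1 -0.039, MRPL37 -0.15, immediate-early mRNAs -0.070, stress response genes -0.0065 and glycolytic enzymes -0.25; with the 3' UTR trend removed splicing regulators -0.14, immediate-early mRNAs -0.11 and glycolytic enzymes -0.031; thinned, GAS5 -0.052; and without 1 library GAS5 -0.18 to 0.21, ASNS -0.61 to 0.056 and immediate-early mRNAs -0.15 to 0.52. The cause of these was not tested. Of 80 named genes past the threshold, 47 kept their call without any 1 library. At the depth, spread and 3 libraries per group had here, 6.78% of simulated 2-fold changes were recovered. That simulation changed 200 genes, against 1591 called in the data, so its adjusted threshold was stricter and the share may be too low.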

Other observations

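Among the tests here, those of chance, of small RNA genes inside counted genes, of annotated NMD transcripts and of upstream ATGs were set before their results were seen, and those of depth, GC content, 3' UTRs and short ribosomal protein transcripts after. Of 128 C/D snoRNAs tested, 120 fell and 0 rose (median log2 fold change -2.07), of 87 H/ACA snoRNAs 64 fell and 0 rose (-1.68), and of 23 small Cajal body RNAs 21 fell and 0 rose (-2.58). The median log2 CPM of H/ACA minus that of C/D snoRNAs was 0.01 ± 0.45 (SD, n = 3) in pre-IP and 0.52 ± 0.24 in p-UPF1 IP, a difference that did not pass (two-sided exact permutation p = 0.2), and differences between the other families were not tested. All 3 vault RNAs fell (median -6.60), and of 22 microRNA genes 19 fell and 0 rose (-4.03). SNORA71B was among the snoRNAs that did not follow, with 3691, 3258 and 2895 counts in pre-IP and 30562, 27792 and 6335 in p-UPF1 IP, and TMM-scaled log2 fold changes of 0.11 for it and 1.57 for SNORA31 (adjusted p = 0.921 and 0.217).

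In 1 regression over 7316 protein-coding genes on the lengths of the coding part and both UTRs and on GC content, the slope of the log2 fold change was 0.476 per doubling of coding length (0.378 to 0.616 over the 9 library pairs), 0.124 per doubling of 3' UTR length (0.102 to 0.149) 0.00023 per doubling of 5' UTR length (-0.0159 to 0.0218) and 0.041 per percent of GC (0.0109 to 0.0502). Slopes per doubling are not shares of the length relation.

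The real split of the 6 libraries called 1591 genes and the highest of the other splits 0, so 1 of the 10 splits gave as many. The splits are too few for a share under 0.05, since the smallest they allow is 0.1.

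The relation with transcript length (rho 0.335) was set against 3 technical or mechanical explanations. Greater depth of the p-UPF1 IP libraries stays open. Over the same 3646 genes the rho was 0.406 with every library thinned to the same number of protein-coding reads and 0.406 at full depth (SD over the library pairs 0.0524). Random thinning leaves the expected ratio of each gene unchanged, so it cannot decide this. Pairs with pre-IP replicate 4, the library with the fewest protein-coding reads (136456), had a rho of 0.301 to 0.335, against 0.219 to 0.280 in the other pairs. That contrast rests on a single library. GC content is argued against, with a rho of 0.400 once the GC trend was removed. Binding of p-UPF1 along the 3' UTR is argued against as the whole origin, since the rho was 0.270 with the 3' UTR trend removed (0.194 to 0.254 over the 9 library pairs). That is a fall from 0.336 over the same genes, by more than the SD over the pairs of 0.0425, so the 3' UTR stays open as a part of it. A different range of fragment sizes in the 2 kinds of library, or p-UPF1 on longer coding regions, may still lie behind it, and the counts per gene hold no fragment lengths to test either.

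The largest decreases among protein-coding genes may in part be reads of small RNA genes inside them, as for CTC1 with its 3 tRNA genes. Of 192 protein-coding genes called lower by more than 4-fold, 7.81% (15, exact 95% interval 4.44% to 12.6%) hold a structured RNA gene, against 4.77% of the 7461 others (odds ratio 1.69, Fisher's exact p = 0.0601). That share is far from most of them, so such reads are argued against as the origin of these decreases as a group and stay open for those 15 genes. The lower cytosolic ribosomal protein mRNAs could follow from their short transcripts. With the length trend of each library removed the list median was -0.53 (-0.885 to -0.12 over the 9 library pairs) in place of -1.22 (-1.55 to -0.737), with a camera adjusted p of 1.2e-05 at the preset correlation. The median stayed below 0 in 9 of 9 pairs, which share libraries and are not independent. The removed trend was smoothed over a span of 0.3 of the genes, and its fit among the shortest transcripts was not checked. Some effect of length may remain in that median, so length as the whole of the decrease stays open. Camera with an estimated correlation cannot decide it either, since the list was past the threshold neither before (adjusted p = 0.210) nor after the removal (0.478). Reads of their pseudogenes and the scaling, on which the sign of the list depends, stay open, and no biological explanation was tested.

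If p-UPF1 selected NMD substrates across the transcriptome, genes with an annotated NMD transcript would be expected to have the higher values at equal transcript length. Within deciles of length, 3455 such genes exceeded 3970 others by a mean of 0.064 on the log2 scale, above 0 in 8 of the 9 library pairs (-0.006 to 0.148). The prediction set beforehand was a difference above 0 in all 9 pairs, and it was not met. Counts per gene cannot separate the NMD transcript from the others of its gene, so binding of those transcripts alone is not excluded. Genes with an upstream ATG in the 5' UTR (3897) differed from those without (3419) by -0.0047 within deciles, above 0 in 6 of the 9 pairs (-0.0451 to 0.0506). The same prediction of all 9 pairs, set beforehand, was not met here either.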
